A study of Mus musculus with 4 samples.

How the data were processed

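The series holds 4 two-colour arrays of mouse RIF-1 cells, per the labels with Cy5 on the knockdown RNA and Cy3 on the control RNA. Each knockdown, Bre1a or Bre1b, was set against cells without knockdown on 1 array and against a mock knockdown of GFP on another. There was no dye swap, so a dye bias of a gene adds to every value against a control. It cancels in the differences between arrays only where it is equal on them. The replicate number in the titles follows the control, with 1 for no knockdown and 2 for mock. No label says that the RNAs came from separate cultures, and the same extracts may have been used on several arrays. The p-values therefore measure only the spread between these arrays, which may be technical.

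The deposited values are log2 ratios of Cy5 over Cy3, found from the values themselves, since the labels name no scale. Image software, background correction, normalization and spot filters are not given in the sources used here. On each array 1 value repeats on 691 to 828 spots. Spots away from it by log2 of a ratio of whole numbers up to 5, within 0.002, numbered 524, 597, 398 and 401 per array, against 216.5, 292.5, 274.5 and 300.0 at slightly shifted positions, and from these the base of the logarithm was read as 2. Whether a loess step was applied is not known, so dye bias that depends on brightness may remain. Spots at the repeated value, within 0.002, include B2m and Vim, and could be spots of ratio 1 or spots saturated in both channels, so they may hold no measured difference. They were kept in the tests and left out in an alternative. Among complete probes 435 had the repeated value on all 4 arrays, and so had all probes of 153 genes. Array medians were -0.006, 0.014, 0.013 and -0.033 for Bre1a against no knockdown, Bre1a against mock, Bre1b against no knockdown and Bre1b against mock, and their SDs 0.993, 0.984, 1.01 and 1.14. Intensities and scanner files were not analysed here, so no spot could be judged by its brightness and no background or loess alternative could be run. The number of arrays limits the precision.

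Probes were named through GEO's annotation of the array platform, with symbols looked up by gene ID in a gene table of the mouse assembly GRCm38.p6, used for names only. Of 38784 probes 22204 had 1 gene symbol, 0 had several and 16580 had none and stay unnamed here. All 22204 symbols were found by gene ID and 0 changed. Values on all 4 arrays were held by 18620 probes, on 1 to 3 arrays by 5058 and on no array by 15106. The 12958 named probes with 4 values were averaged per symbol into 8676 genes, of which 2821 had several probes. Probes of 1 gene differed by at least 0.5 in opposite directions in 15 genes for Bre1a and 37 for Bre1b, with a median range of 0.168 and 0.188 in log2. All columns of values were mapped to a sample.

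Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, two-sided, Benjamini-Hochberg over 8676 genes, threshold 0.05). The model had a coefficient per knockdown and a term for the control, coded so that each knockdown is the mean over both controls. It leaves 1 residual degree of freedom, with 1.57 prior degrees of freedom. Contrasts were each knockdown, Bre1a minus Bre1b, and mock minus no knockdown. The fit without the control term has 2 residual degrees of freedom and is printed beside the counts. Since the control term is the replicate number as a block, that fit is also the one without a replicate block. The spread between arrays of 1 knockdown includes the difference between the controls, which the main model takes out.

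Gene lists were tested with camera at a preset correlation of 0.01, adjusted over the 22 lists with at least 5 measured genes. A total of 24 lists was fixed: the 2 targets, H2B ubiquitination machinery, H3K4 and H3K79 methyltransferases, homologous recombination, damage checkpoint, p53 targets, DNA replication, G2 and mitosis, histone genes, interferon and antigen presentation, cytokines and NF-kB targets, extracellular matrix, hypoxia and glycolysis, integrated stress response, cholesterol, ribosomal proteins, oxidative phosphorylation, heat shock and oxidative stress, immediate early genes, Hox genes, and markers of leukocytes, epithelium, endothelium, and muscle or neural cells. Of 28 leukocyte markers 3 were measured, so that list was not tested. With a correlation estimated from the residuals no list was called in any comparison. That setting rests on 1 residual degree of freedom, and its lowest camera adjusted p per comparison ran from 0.511 to 0.683. It could hardly call any list, so a miss there does not show that a list was unchanged. Fry, which tests a list on its own, called 13 lists for Bre1a, of which 9 were also called by camera, and 0 for the other contrasts. The lowest fry adjusted p was 0.0527 for Bre1b, 0.0674 between the knockdowns and 0.124 between the controls. In 10 of the 88 list tests, 0 of them called, the median, the mean and the direction of the test were not of 1 sign.

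The named genes follow a rule. They are Rnf20 and Rnf40, the 10 highest and 10 lowest genes of each knockdown and of Bre1a minus Bre1b, and 5 and 5 for the controls, ranked by the smaller in size of the 2 values where these have the same sign. Added to these are up to 4 members per list with the largest test statistic. Names of predicted or uncharacterised transcripts were passed over. Lists, design, rule and most alternatives were set before the data were examined.

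The scripts were tested on simulated data with 8676 genes and 200 changed. For Bre1a against control they recovered 82% of log2 changes of 1 and 95% of log2 changes of 2, with 9.23% of calls among unchanged genes. For Bre1a minus Bre1b they recovered 51% and 86%, with 6.80% of calls among unchanged genes. In comparisons without a simulated change 0 genes were called. A raised interferon list was found, with 0 other lists called. Simulated genes were independent of each other, with variances drawn from the prior of the fit and no difference between the controls. The simulation could therefore not show false calls that arise where genes of a list move together. To see what shared controls give, unchanged cells were simulated from the spread between the controls. Alternatives were other fits, scalings, filters, thresholds and probe choices, and the arrays left out in turn. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.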

Results

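RNA of RIF-1 cells, a mouse line derived from a radiation-induced fibrosarcoma, was compared after RNA interference against Bre1a (gene Rnf20) or Bre1b (gene Rnf40). The proteins of these genes pair to form the E3 ubiquitin ligase of histone H2B. The data are 4 two-colour arrays, 2 per knockdown. Knockdown RNA carried Cy5 and control RNA carried Cy3 on all 4. Of the 2 arrays of each knockdown, 1 had cells without knockdown as the control and 1 had cells with a mock knockdown aimed at GFP. The arrays hold 38784 spots each, of which 20621 had a value for Bre1a against no knockdown, 22255 for Bre1a against mock, 20629 for Bre1b against no knockdown and 19874 for Bre1b against mock. Tests covered 8676 named genes with values on all 4 arrays. The values are log2 ratios of knockdown over control, given as the mean ± SD over 2 arrays (n = 2), so that the SD includes the difference between the controls. The number of arrays limits the precision.

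Each target gene was lower on the arrays of its own knockdown. Rnf20 was at -1.48 ± 0.18 on the Bre1a arrays (35.9% of control, n = 2, limma adjusted p = 0.0212), with -1.60 against no knockdown and -1.35 against mock. Rnf40 was at -1.36 ± 0.18 on the Bre1b arrays (38.9% of control, n = 2, limma adjusted p = 0.00944), with -1.49 and -1.23. The partner gene went the other way in each case. Rnf40 was at 0.41 ± 0.34 after Bre1a knockdown (133% of control, limma adjusted p = 0.0349), and Rnf20 was at 0.47 ± 0.06 after Bre1b knockdown (138% of control, limma adjusted p = 0.0152). Without the control term none of these 4 values passed the threshold, with adjusted p = 0.0577 for Rnf20 on the Bre1a arrays and 0.052 for Rnf40 on the Bre1b arrays. A further Rnf40 spot had values on the Bre1a arrays only, -1.92 and 0.56, which differ in sign, and was not used.

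**Figure D1:**
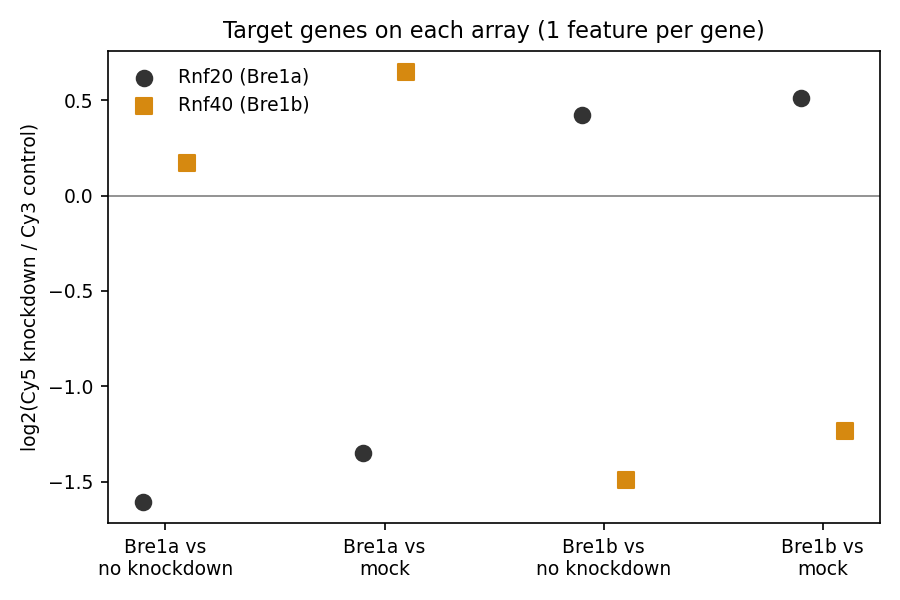
Log2 ratio of knockdown (Cy5) over control (Cy3) for Rnf20 (circles) and Rnf40 (squares) on each of the 4 arrays, 1 spot per gene, with no error bar since each point is 1 array. Rnf20 lies at -1.60 and -1.35 on the Bre1a arrays and Rnf40 at -1.49 and -1.23 on the Bre1b arrays.

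On the Bre1a arrays, genes of cholesterol synthesis, cytokine signalling, interferon response, extracellular matrix and hypoxia were lower than in the controls. Genes of the redox response were higher. Without a dye swap, a dye bias of these genes cannot be told apart from an effect of the knockdown. Among the cholesterol genes 2 of 20 measured genes rose and 17 fell (2 and 17 adjusted over the list alone), with a list median of -0.95; camera adjusted p = 1.08e-06, and adjusted p = 0.511 with an estimated correlation. The synthesis enzymes Cyp51 (-1.53 ± 0.15), Idi1 (-1.41 ± 0.18) and Hsd17b7 (-1.32 ± 0.32) and the fatty acid desaturase Scd1 (-1.52 ± 0.62) fell. Of cytokines, chemokines and NF-kB targets, 3 of 28 measured genes rose and 18 fell (3 and 19 adjusted over the list alone); camera adjusted p = 0.000103, and adjusted p = 0.511 with an estimated correlation. They included the chemokine Cxcl5 (-2.01 ± 0.41), the NF-kB inhibitors Tnfaip3 (-1.43 ± 0.49) and Nfkbie (-1.24 ± 0.42) and Il11 (-1.39 ± 1.00). In the interferon and antigen presentation list 1 of 36 measured genes rose and 22 fell (1 and 24 adjusted over the list alone); camera adjusted p = 9.83e-06, and adjusted p = 0.511 with an estimated correlation. Examples were the GTPase Igtp (-0.93 ± 0.27), the immunoproteasome subunit Psmb8 (-0.63 ± 0.38) and Ifit3 (-0.98 ± 1.08).

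Matrix genes also fell on balance, since 10 of 48 measured genes rose and 24 fell (10 and 24 adjusted over the list alone); camera adjusted p = 0.0395, and adjusted p = 0.511 with an estimated correlation. With arrays centred on their medians this list had adjusted p = 0.0633. Periostin (Postn) was at -4.32 ± 0.00, about 20.0-fold lower on both arrays, and the collagen crosslinking enzymes Lox (-1.27 ± 0.14) and Loxl1 (-1.21 ± 0.48) fell too. In the hypoxia and glycolysis list 0 of 27 measured genes rose and 14 fell (1 and 14 adjusted over the list alone); camera adjusted p = 0.0146, and adjusted p = 0.511 with an estimated correlation. Carbonic anhydrase 9 (Car9) was at -2.54 ± 1.20, followed by the lactate transporter Slc16a3 (-0.93 ± 0.19), the growth factor Vegfa (-0.76 ± 0.04) and the hexokinase Hk2 (-0.71 ± 0.04). By contrast, in the heat shock and oxidative stress list 13 of 22 measured genes rose and 0 fell (14 and 0 adjusted over the list alone); camera adjusted p = 0.000103, and adjusted p = 0.511 with an estimated correlation. The chaperone Hspb1 (1.33 ± 0.72) and the glutathione enzymes Gclm (0.92 ± 0.26) and Gsr (0.66 ± 0.09) rose.

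Lists of proliferation genes were called higher after Bre1a knockdown. For DNA replication 19 of 50 measured genes rose and 2 fell (20 and 2 adjusted over the list alone), with Ccne2 (0.59 ± 0.03), Slbp (0.56 ± 0.04) and Mcm5 (0.46 ± 0.24) among those that rose; camera adjusted p = 0.0014, and adjusted p = 0.511 with an estimated correlation. For G2 and mitosis 19 of 51 measured genes rose and 1 fell (19 and 1 adjusted over the list alone), with Kif11 (0.42 ± 0.12), Foxm1 (0.40 ± 0.05) and Ttk (0.38 ± 0.32) as examples; camera adjusted p = 0.0014, and adjusted p = 0.511 with an estimated correlation. The medians against no knockdown and against mock were 0.05 and 0.30 for G2 and mitosis, a list that was itself lower in mock cells. For DNA replication they were 0.13 and 0.22, and there the difference between the controls was not called (camera adjusted p = 0.126). In the p53 target list 15 of 34 measured genes rose and 5 fell (17 and 5 adjusted over the list alone); camera adjusted p = 0.039, and adjusted p = 0.511 with an estimated correlation. The members with the largest test statistic were mostly ones that fell, namely Plk2 (-2.08 ± 0.20), Dram1 (-1.47 ± 0.16) and Fas (-1.13 ± 0.63), beside Btg2 (0.88 ± 0.70), which rose. Respiratory chain genes moved little, with a median of 0.12, while 19 of 69 measured genes rose and 1 fell (9 and 1 adjusted over the list alone), Ndufa4 (0.76 ± 0.27) and Atp5md (0.51 ± 0.07) among them; camera adjusted p = 0.000103, and adjusted p = 0.511 with an estimated correlation. For the H2B ubiquitination machinery 8 of 19 measured genes rose and 0 fell (9 and 0 adjusted over the list alone), Usp12 (0.39 ± 0.21) and Wac (0.32 ± 0.13) among them; camera adjusted p = 0.0171, and adjusted p = 0.511 with an estimated correlation. Replication-dependent histone genes, whose near-identical copies the probes may not separate, gave a count in which 12 of 42 measured genes rose and 2 fell (9 and 2 adjusted over the list alone); camera adjusted p = 0.00158, and adjusted p = 0.511 with an estimated correlation. Their median was -0.10 against no knockdown and 0.46 against mock, with H3c7 (1.44 ± 1.26) and H2bc8 (1.00 ± 0.70) as examples. Without the control term the list had adjusted p = 0.0795. In the ribosomal protein list 7 of 67 measured genes rose and 3 fell (0 and 0 adjusted over the list alone); camera adjusted p = 0.0395, and adjusted p = 0.702 with an estimated correlation. Of its genes, 36 sat at the repeated value of each array, and without such spots its adjusted p was 0.461, and with a single probe per gene 0.0884. Against no knockdown and against mock the medians were -0.22 and -0.41 for interferon, -0.11 and -0.25 for matrix, -0.16 and -0.38 for hypoxia, -0.72 and -1.24 for cholesterol and 0.23 and 0.42 for heat shock genes. By fry the H2B machinery, histone, ribosomal and respiratory chain lists did not pass (adjusted p = 0.196, 0.109, 0.428 and 0.0656).

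No call was made for 9 other lists (camera adjusted p from 0.115 to 0.572). They were the H3K4 and H3K79 methyltransferases, homologous recombination, damage checkpoint, integrated stress response, immediate early genes, Hox genes, and epithelial, endothelial and muscle or neural markers (adjusted p = 0.281, 0.118 and 0.177 for these markers). By fry, which tests a list on its own, the H3K4 and H3K79, recombination, Hox and epithelial lists passed (adjusted p = 0.0342, 0.034, 0.034 and 0.0382). Single members of them changed, such as the H3K79 methyltransferase Dot1l (0.95 ± 0.40), the recombination genes Dna2 (1.62 ± 0.18) and Fancm (0.81 ± 0.20), the transcription factor Klf2 (1.51 ± 0.37) and the keratin Krt18 (-1.21 ± 0.02). Single genes were ranked by the smaller of the 2 values. The highest included the late cornified envelope genes Lce1g (4.44 ± 0.17), Lce1h (4.33 ± 0.90), Lce1e (3.63 ± 0.22) and Lce1i (2.57 ± 0.27), the glutathione transferase Gsta2 (4.13 ± 0.04), Sprr2a1 (3.70 ± 0.40) and Crct1 (2.61 ± 0.29) and the chemokine Ppbp (2.91 ± 0.60). No list of cornified envelope genes was tested. Sequences of the Lce1 genes are alike, so their probes are not independent. Selp was at 3.38 ± 1.35 and Prr9 at 3.09 ± 1.05, and neither passed the test (limma adjusted p = 0.0687 and 0.0706). Besides Postn, the lowest genes were Myo15 (-4.90 ± 0.31), Saa3 (-3.56 ± 0.03), Gda (-3.47 ± 0.56), Rad9b (-3.19 ± 0.32), Casp4 (-3.11 ± 0.04), Ubd (-3.02 ± 0.27), Ncf4 (-2.83 ± 0.17), Trem2 (-2.66 ± 0.15) and Nrep (-2.59 ± 0.24). Of these Saa3 is an acute phase protein, Casp4 an inflammatory caspase, Ncf4 a subunit of the phagocyte oxidase and Trem2 a myeloid receptor. Each of the highest and lowest genes rested on 1 spot, except Casp4 with 2.

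Over all genes limma with Benjamini-Hochberg adjustment called 3551 of 8676 for Bre1a, 1828 higher and 1723 lower. Called genes named for this knockdown had adjusted p from 0.0212 to 0.0391. Without the control term 1 gene was called higher and 1 lower, so that nearly all calls rest on taking out the difference between the controls. With the arrays scaled to 1 spread, 530 were called higher and 991 lower. At least 2-fold on both arrays in 1 direction were 42 genes higher and 157 lower, while 16 were at least 2-fold in opposite directions.

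On the Bre1b arrays cholesterol and interferon genes were likewise lower than in the controls, and p53 targets, immediate early genes and histone genes higher. Here too a dye bias cannot be told apart from an effect of the knockdown. By fry no list was called for Bre1b, though the cholesterol, interferon, p53 and G2 and mitosis lists came close (adjusted p = 0.0527 each). Among the cholesterol genes 1 of 20 measured genes rose and 18 fell (1 and 18 adjusted over the list alone), with a list median of -0.99; camera adjusted p = 1.69e-06, and adjusted p = 0.635 with an estimated correlation. The sterol regulator Insig1 (-2.10 ± 0.42), the synthesis enzymes Hmgcs1 (-1.55 ± 0.19) and Idi1 (-1.42 ± 0.17) and Scd1 (-1.88 ± 0.68) fell. Of the interferon and antigen presentation genes 2 of 36 measured genes rose and 24 fell (2 and 24 adjusted over the list alone); camera adjusted p = 4.41e-05, and adjusted p = 0.635 with an estimated correlation. The nuclear body protein Sp100 (-2.06 ± 0.64), the GTPase Gbp2 (-1.62 ± 0.71) and Psmb8 (-1.52 ± 0.37) were among the genes that fell.

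In the p53 target list 22 of 34 measured genes rose and 5 fell (25 and 5 adjusted over the list alone), with Btg2 (1.70 ± 0.69), Mdm2 (1.30 ± 0.21) and Ccng1 (1.07 ± 0.13) rising and the kinase Plk2 (-1.85 ± 0.21) falling; camera adjusted p = 0.000785, and adjusted p = 0.635 with an estimated correlation. Mdm2 is the ubiquitin ligase of p53. For immediate early genes 20 of 28 measured genes rose and 2 fell (20 and 3 adjusted over the list alone); camera adjusted p = 0.00569, and adjusted p = 0.635 with an estimated correlation. The phosphatase Dusp1 (1.56 ± 0.43), the growth factor Ereg (1.53 ± 0.54) and the nuclear receptor Nr4a1 (1.28 ± 0.69) rose. Of the integrated stress and unfolded protein response genes 11 of 30 measured genes rose and 2 fell (10 and 2 adjusted over the list alone); camera adjusted p = 0.0447, and adjusted p = 0.635 with an estimated correlation. The transcription factors Atf3 (2.58 ± 1.26) and Ddit3 (0.86 ± 0.12) and the phosphatase regulator Ppp1r15a (0.86 ± 0.07) rose. Without spots at the repeated value the list had adjusted p = 0.0569, with the arrays scaled to 1 spread 0.0608 and with a single probe per gene 0.0586. In the heat shock and oxidative stress list 13 of 22 measured genes rose and 2 fell (13 and 2 adjusted over the list alone), with Hspb1 (1.35 ± 0.84) and Hmox1 (0.93 ± 0.14) as examples; camera adjusted p = 0.019, and adjusted p = 0.635 with an estimated correlation.

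G2 and mitosis genes were lower after Bre1b knockdown, as 0 of 51 measured genes rose and 24 fell (0 and 17 adjusted over the list alone); camera adjusted p = 0.000454, and adjusted p = 0.635 with an estimated correlation. Examples were the kinase Pbk (-0.82 ± 0.04), survivin (Birc5, -0.72 ± 0.24) and the kinetochore gene Nuf2 (-0.49 ± 0.14). The list median was -0.34 against no knockdown and -0.06 against mock, whose cells were themselves lower in this list. Of the replication-dependent histone genes 28 of 42 measured genes rose and 2 fell (28 and 2 adjusted over the list alone); camera adjusted p = 3.45e-05, and adjusted p = 0.635 with an estimated correlation. Their median was 0.29 against no knockdown and 1.19 against mock, with H2bc4 (1.25 ± 0.35), H2bc22 (1.02 ± 0.37) and H4c9 (1.05 ± 0.68) as examples. With the controls in the same order, medians were -0.44 and -0.75 for interferon, -0.72 and -1.17 for cholesterol, 0.11 and 0.18 for integrated stress, 0.14 and 0.45 for heat shock and 0.34 and 0.54 for immediate early genes. For the H2B ubiquitination machinery 11 of 19 measured genes rose and 1 fell (11 and 1 adjusted over the list alone), the adaptor Wac (0.62 ± 0.10) rising and the deubiquitinase Usp46 (-1.21 ± 0.03) falling; camera adjusted p = 0.0118, and adjusted p = 0.635 with an estimated correlation.

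Homologous recombination genes did not pass as a list (camera adjusted p = 0.0643, and 0.0394 without the control term), although 6 of 32 measured genes rose and 16 fell (6 and 16 adjusted over the list alone). Members that fell included the Fanconi gene Fancg (-1.55 ± 0.18). Cytokine genes went both ways, since 9 of 28 measured genes rose and 7 fell (9 and 7 adjusted over the list alone) (camera adjusted p = 0.922). Here Ccl5 (2.22 ± 1.63), Il11 (1.73 ± 0.99) and Ptgs2 (1.49 ± 0.47) rose and the protease Mmp9 (-1.58 ± 0.41) fell. Matrix genes were mixed too (camera adjusted p = 0.305), with Thbs1 (1.65 ± 0.15) and Ccn2 (1.91 ± 1.27) rising and Fbln2 (-2.09 ± 0.64) falling. The other 10 lists were not called either: H3K4 and H3K79 methyltransferases, damage checkpoint, DNA replication, hypoxia, ribosomal proteins, respiratory chain, Hox genes, and epithelial, endothelial and muscle or neural markers. Over the 13 lists without a call the camera adjusted p ran from 0.0643 to 0.922, with 0.305, 0.0908 and 0.859 for the 3 marker lists, and without the control term the endothelial list had 0.0384. Single members of them changed, such as Dot1l (0.87 ± 0.58) and Hoxc13 (1.26 ± 0.13) and the endothelial nitric oxide synthase Nos3 (-2.61 ± 0.26).

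Ranked in the same way, the highest single genes after Bre1b knockdown included Lce1g (4.35 ± 0.19), Lce1h (4.29 ± 0.63), Lce1e (3.60 ± 0.39) and Lce1i (3.05 ± 0.17). Others were the chemokines Cxcl2 (3.68 ± 0.63) and Ppbp (3.00 ± 0.04), P-selectin (Selp, 6.08 ± 3.95), the protease inhibitor Serpinb2 (3.67 ± 1.13) and the cytokine Il24 (2.78 ± 0.27), beside Fam180a (3.31 ± 0.49). Selp differed widely between the arrays, at 3.29 against no knockdown and 8.88 against mock. The lowest were Lrrtm2 (-7.59 ± 1.68), Myo15 (-6.48 ± 0.93), Kctd12b (-6.01 ± 0.70), Olfr1006 (-3.94 ± 0.14), Tbx10 (-3.80 ± 1.30), Dnajc22 (-3.52 ± 0.24) and P2rx6 (-2.97 ± 0.20). With them came the histone deacetylase Hdac11 (-3.45 ± 0.01), the hexosamine enzyme Gfpt2 (-3.11 ± 0.13) and the lysyl oxidase relative Loxl3 (-3.10 ± 0.41). Each of these highest and lowest genes rested on 1 spot, except P2rx6 with 2. Olfr1006 is an olfactory receptor gene, and the value table holds no intensities that would tell how bright its spot was.

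Limma with Benjamini-Hochberg adjustment called 5244 of 8676 genes for Bre1b, 2800 higher and 2444 lower. Called genes named for this knockdown had adjusted p from 0.00944 to 0.0311. Without the control term 37 were called higher and 125 lower, and with the arrays scaled to 1 spread 1628 were called, 716 higher and 912 lower. At least 2-fold on both arrays were 72 genes higher and 275 lower, against 6 in opposite directions.

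**Figure D2:**
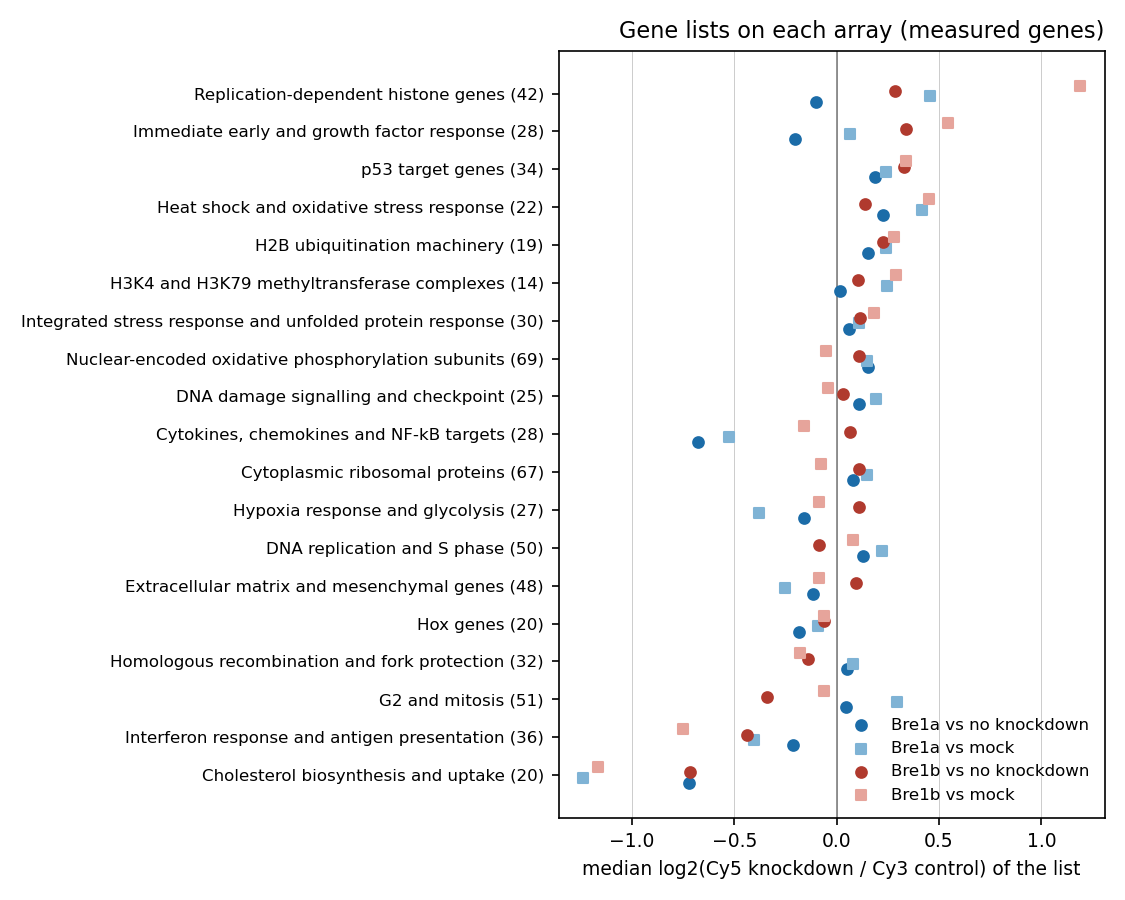
Median log2 ratio of knockdown over control of the measured genes of 19 gene lists on each of the 4 arrays, blue for Bre1a and red for Bre1b, circles for no knockdown and squares for mock as the control. The cholesterol list lies between -1.24 and -0.72 on all 4 arrays, while the histone list runs from -0.10 to 1.19.

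The knockdowns were compared with each other through their shared controls, a contrast in which a dye bias of a gene cancels if it is equal on all arrays. The arrays of the knockdowns differ in spread and in the month of their image records, so some bias may remain. Values are Bre1a minus Bre1b, as the mean ± SD of the differences within no knockdown and within mock (n = 2). Both differences may compare the same extracts of the knockdowns, so their SD may be technical. Cytokine genes were lower after Bre1a than after Bre1b knockdown: 3 of 28 measured genes were higher and 14 lower with Bre1a (4 and 19 adjusted over the list alone); camera adjusted p = 0.00125, and adjusted p = 0.631 with an estimated correlation. They included Il11 (-3.12 ± 0.01), Cxcl5 (-2.03 ± 0.07), Tnfaip3 (-1.83 ± 0.04) and Ptgs2 (-1.69 ± 0.02). Immediate early genes did likewise, as 2 of 28 measured genes were higher and 13 lower with Bre1a (2 and 14 adjusted over the list alone); camera adjusted p = 0.00161, and adjusted p = 0.631 with an estimated correlation. Their examples were Fosb (-1.07 ± 0.01), Fos (-1.98 ± 0.03) and Nr4a1 (-1.65 ± 0.05). Of the p53 targets 1 of 34 measured genes was higher and 13 lower with Bre1a (1 and 18 adjusted over the list alone), with Btg2 (-0.82 ± 0.01) and Gadd45a (-0.67 ± 0.03) lower; camera adjusted p = 0.00289, and adjusted p = 0.631 with an estimated correlation. For histone genes 1 of 42 measured genes was higher and 20 lower with Bre1a (1 and 22 adjusted over the list alone), H2bc4 (-1.04 ± 0.02) and H4c9 (-1.02 ± 0.05) among them; camera adjusted p = 0.00108, and adjusted p = 0.631 with an estimated correlation.

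Mitotic and repair genes were higher after Bre1a than after Bre1b knockdown. In the G2 and mitosis list 20 of 51 measured genes were higher and 0 lower with Bre1a (31 and 0 adjusted over the list alone), with Birc5 (0.96 ± 0.05), Cenpe (0.86 ± 0.09) and Kif11 (0.66 ± 0.02); camera adjusted p = 5.20e-08, and adjusted p = 0.631 with an estimated correlation. In homologous recombination 13 of 32 measured genes were higher and 2 lower with Bre1a (19 and 3 adjusted over the list alone), with the Fanconi genes Fanca (0.71 ± 0.06) and Fanci (0.70 ± 0.06) and the nuclease Dna2 (1.51 ± 0.31); camera adjusted p = 0.00108, and adjusted p = 0.631 with an estimated correlation. In DNA replication 11 of 50 measured genes were higher and 2 lower with Bre1a (16 and 3 adjusted over the list alone), with the ligase Lig1 (0.57 ± 0.05) and E2f2 (0.70 ± 0.11); camera adjusted p = 0.00232, and adjusted p = 0.631 with an estimated correlation. Interferon genes split, as 10 of 36 measured genes were higher and 6 lower with Bre1a (18 and 7 adjusted over the list alone); camera adjusted p = 0.0319, and adjusted p = 0.631 with an estimated correlation. Of them Gbp2 (1.27 ± 0.00) and Sp100 (1.49 ± 0.09) were higher and Ifit1 (-1.17 ± 0.01) and Cxcl10 (-1.31 ± 0.08) lower with Bre1a. The interferon list had adjusted p = 0.433 with the arrays scaled to 1 spread and 0.0807 without the control term. Of the ribosomal protein genes 3 of 67 measured genes were higher and 1 lower with Bre1a (0 and 0 adjusted over the list alone), with a list median of 0.10; camera adjusted p = 0.0262, and adjusted p = 0.737 with an estimated correlation. Of the respiratory chain genes 4 of 69 measured genes were higher and 0 lower with Bre1a (0 and 0 adjusted over the list alone), with a list median of 0.09; camera adjusted p = 0.0459, and adjusted p = 0.631 with an estimated correlation. Without spots at the repeated value their adjusted p were 0.340 and 0.0926, and the respiratory chain list had 0.0815 without the control term, 0.0567 with centred arrays and 0.0852 with a single probe per gene. Within no knockdown and within mock their medians were -0.03 and 0.23 for ribosomal proteins and 0.01 and 0.13 for the respiratory chain. The ribosomal medians were 0.079 and 0.148 on the Bre1a arrays and 0.11 and -0.079 on the Bre1b arrays. Each was, after rounding, the repeated value of its array, so these ribosomal differences may hold no measured change. The other 12 lists were not called (camera adjusted p from 0.10 to 0.930), the cholesterol list among them with adjusted p = 0.10. With the arrays scaled to 1 spread the matrix, hypoxia, heat shock and muscle or neural lists passed (adjusted p = 0.0226, 0.0262, 0.0161 and 0.041). Each had adjusted p = 0.73 there with an estimated correlation. Members of the 12 lists that differed included the stress genes Atf3 (-3.07 ± 0.05) and Ddit3 (-0.88 ± 0.10), the hypoxia genes Hk2 (-1.02 ± 0.03) and Vegfa (-0.96 ± 0.05) and the matrix genes Tnc (-1.70 ± 0.01) and Mmp10 (-1.66 ± 0.01).

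Of single genes, the chemokine Cxcl2 (-4.57 ± 0.44) and the cytochrome Cyp1b1 (-4.56 ± 0.56) were lowest with Bre1a relative to Bre1b, followed by Zhx2 (-3.29 ± 0.19), Stx3 (-3.01 ± 0.33), Ror1 (-3.54 ± 1.10), Postn (-2.83 ± 0.21) and Dlg2 (-2.65 ± 0.19) and by Il11 and Atf3, given above. Saa3 was at -3.92 ± 1.60 and did not pass (limma adjusted p = 0.0565). Highest were Kctd12b (5.22 ± 1.41), Ypel1 (3.60 ± 1.13), Afap1l2 (3.57 ± 0.62), Gp9 (3.49 ± 0.84), Olfr1006 (2.78 ± 0.01), Sema6c (2.71 ± 0.61) and Sp110 (2.66 ± 0.26) and the pyrimidine catabolic enzyme Dpyd (3.00 ± 0.70). Lrrtm2 (6.77 ± 3.43) and Adam12 (4.25 ± 2.51) did not pass (limma adjusted p = 0.0737 and 0.0916). Rnf20 was at -1.94 ± 0.12 and Rnf40 at 1.77 ± 0.15. Limma called 1014 genes higher and 1147 lower with Bre1a, with adjusted p from 0.0372 to 0.0453 for the called genes named here. Without the control term limma called 0 genes (1286 at an unadjusted p under 0.05), and with the arrays scaled to 1 spread it called 0. The image records in the labels' descriptions place the Bre1a pair and the Bre1b pair of arrays in different months, so a batch by month and the knockdown cannot be told apart here.

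**Figure D3:**
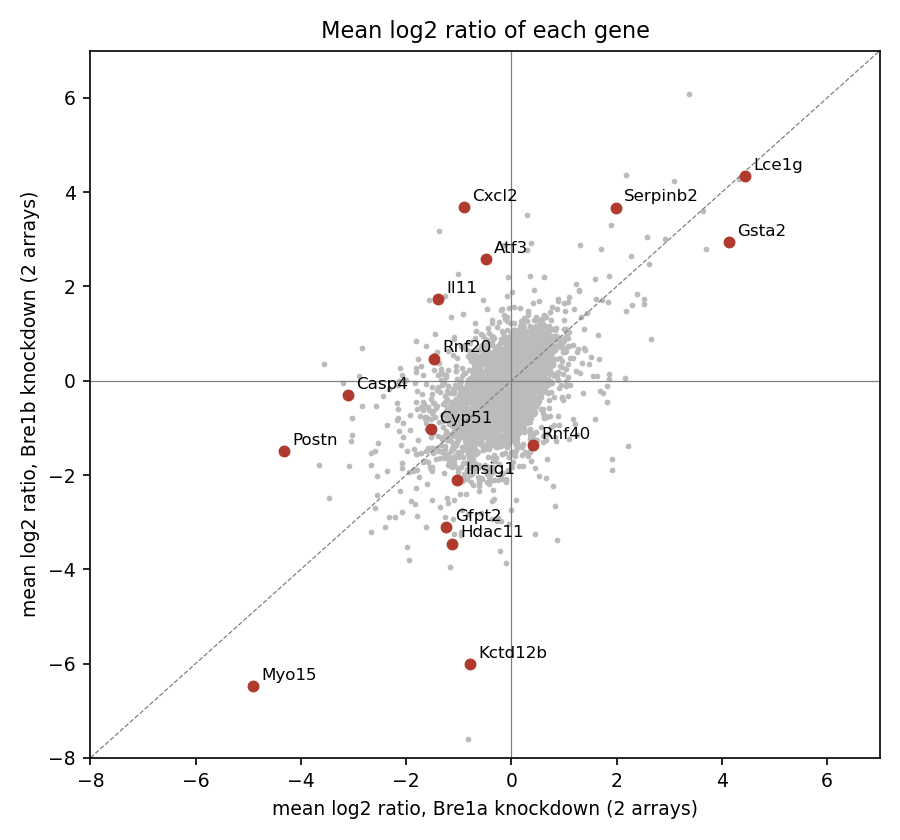
Mean log2 ratio of knockdown over control of 8676 genes, Bre1a on the horizontal and Bre1b on the vertical axis, each the mean of 2 arrays, with the line of equal values dashed and some genes named. Lce1g lies high on both axes at 4.44 and 4.35, while Cxcl2 lies at -0.90 for Bre1a and 3.68 for Bre1b.

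Across genes the arrays of 1 knockdown correlated with r = 0.516 (Bre1a) and 0.753 (Bre1b), and those with 1 control with r = 0.396 (no knockdown) and 0.683 (mock). Arrays that share neither correlated with r = 0.228 (Bre1a against no knockdown with Bre1b against mock) and 0.486 (Bre1a against mock with Bre1b against no knockdown). Genes are not independent replicates, so no p is given. In simulated unchanged cells the arrays of 1 knockdown gave r = 0.527 (Bre1a) and 0.491 (Bre1b). There the shared control alone gave 0.504 and 0.495, and arrays that share neither gave 0.00347 and 0.0148. The simulation was a single draw of independent RNAs with equal spread per gene, without array noise or dye bias. Its correlations follow from that construction, whatever the data, and are no measured null for the observed ones. With a shared control the observed covariances were 0.123 and 0.292, where the simulation gave 0.110 and 0.106. At least 2-fold higher on all 4 arrays were 22 genes, among them Lce1g, Lce1h, Lce1e, Gsta2, Ppbp and Serpinb2. Independent lists would share 0.349 genes, and simulated unchanged cells with the shared controls gave 19. The simulated lists were of another length, 67 and 71 genes against 42 and 72 observed, so the 19 is no like-for-like value. At least 2-fold lower on all 4 were 55 genes, among them Myo15, Postn, Plk2, Scd1, Idi1 and Hmgcs1, where independent lists would share 4.98 and the simulation gave 13, from lists of 78 and 60 against 157 and 275 observed. Part of this overlap may come from the shared controls, which could not be split.

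The mock control differed from cells without knockdown, estimated as the difference between the arrays of each knockdown (n = 2 differences, mock minus no knockdown). Both differences may compare the same extracts of the controls, so their SD may be technical. Mitotic genes were lower in mock cells: in the G2 and mitosis list 0 of 51 measured genes were higher and 8 lower in mock (0 and 26 adjusted over the list alone); camera adjusted p = 9.70e-08, and adjusted p = 0.683 with an estimated correlation. The kinases Plk1 (-0.74 ± 0.04) and Aurka (-0.57 ± 0.09) and the kinetochore gene Ndc80 (-0.65 ± 0.06) were among them, and 46 of 51 genes were lower in both estimates. For histone genes 1 of 42 measured genes was higher and 24 lower in mock (1 and 29 adjusted over the list alone), with H3c7 (-1.69 ± 0.14) and H4c3 (-1.02 ± 0.06); camera adjusted p = 6.96e-07, and adjusted p = 0.683 with an estimated correlation. Cholesterol genes were higher in mock cells, as 7 of 20 measured genes were higher and 0 lower in mock (17 and 0 adjusted over the list alone); camera adjusted p = 2.41e-06, and adjusted p = 0.683 with an estimated correlation. Examples were Scd1 (0.92 ± 0.06), Lss (1.00 ± 0.18) and Insig1 (0.57 ± 0.04). Of the hypoxia genes 6 of 27 measured genes were higher and 0 lower in mock (12 and 2 adjusted over the list alone), with Car9 (1.68 ± 0.03) and P4ha1 (0.84 ± 0.01); camera adjusted p = 0.0103, and adjusted p = 0.683 with an estimated correlation.

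Of the immediate early genes 2 of 28 measured genes were higher and 4 lower in mock (3 and 15 adjusted over the list alone), with Nr4a1 (-1.01 ± 0.05) and Fos (-0.93 ± 0.03) lower; camera adjusted p = 0.0103, and adjusted p = 0.738 with an estimated correlation. Of the heat shock and oxidative stress genes 1 of 22 measured genes was higher and 5 lower in mock (1 and 8 adjusted over the list alone), with Hspb1 (-1.11 ± 0.12) and Txnrd1 (-0.69 ± 0.05) lower; camera adjusted p = 0.0198, and adjusted p = 0.683 with an estimated correlation. Of the H3K4 and H3K79 methyltransferase genes 0 of 14 measured genes were higher and 1 lower in mock (0 and 1 adjusted over the list alone), namely Cxxc1 (-0.66 ± 0.05); camera adjusted p = 0.0314, and adjusted p = 0.683 with an estimated correlation. With a single probe per gene this list had adjusted p = 0.0716. Of the ribosomal protein genes 1 of 67 measured genes was higher and 1 lower in mock (1 and 0 adjusted over the list alone); camera adjusted p = 0.0314, and adjusted p = 0.878 with an estimated correlation. Of the respiratory chain genes 2 of 69 measured genes were higher and 0 lower in mock (0 and 0 adjusted over the list alone); camera adjusted p = 0.0198, and adjusted p = 0.738 with an estimated correlation. On the Bre1a and the Bre1b arrays the medians were -0.07 and 0.19 for ribosomal proteins and 0.04 and 0.18 for the respiratory chain. The ribosomal medians lie at the differences between the repeated values of the arrays, so they may hold no measured change. Without spots at the repeated value the ribosomal list had adjusted p = 0.0677. With the arrays scaled to 1 spread 4 of the 9 list calls were lost, those of the cholesterol, heat shock, immediate early and H3K4 and H3K79 lists (adjusted p = 0.263, 0.212, 0.15 and 0.0829). Interferon genes were not called as a list (camera adjusted p = 0.093), though Ifit1 (-2.27 ± 0.01) and Ifit3 (-1.46 ± 0.09) were lower and Gbp2 (1.00 ± 0.00) higher. The chemokine Ccl5 (-2.25 ± 0.07) and Il11 (-1.41 ± 0.01) were lower. Over the 13 lists without a call the camera adjusted p ran from 0.0790 to 0.924.

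Highest in mock cells were the carboxylesterase Ces1g (4.64 ± 0.03), Gsap (3.43 ± 0.31) and Chchd10 (2.90 ± 0.30) and smooth muscle actin (Acta2, 2.92 ± 0.18). P2ry12 (3.90 ± 1.68) did not pass (limma adjusted p = 0.0681). Lowest were the surface protein Cd24a (-4.27 ± 0.98), the antiviral enzyme Oas1a (-3.58 ± 0.73), the cystine transporter Slc7a11 (-2.92 ± 0.31) and the keratin Krt16 (-3.09 ± 0.80), with Ifit1 given above. Of list members outside this ranking, the matrix regulator Ccn2 (1.89 ± 0.14) and the keratin Krt8 (1.69 ± 0.18) were higher. In the same way Tnc (-1.42 ± 0.01) and Atf3 (-1.82 ± 0.05) were lower. Neither target gene passed, with Rnf20 at -0.17 ± 0.12 and Rnf40 at -0.37 ± 0.15 (limma adjusted p = 0.198 and 0.0842). Limma with Benjamini-Hochberg adjustment called 630 genes higher and 531 lower in mock, with adjusted p from 0.0475 to 0.0481 for the called genes named here. Scaled to 1 spread, or with quantile normalization, limma called 0 genes, and 3854 had an unadjusted p under 0.05 in the fit as reported.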

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

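The tests of array spread and of month were chosen after the results were seen, and those of the differences between the knockdowns before.

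Of 35 genes named for the knockdowns, 17 had a called difference between Bre1a and Bre1b (limma, Benjamini-Hochberg), against 2161 of all 8676 genes. Lower with Bre1a, as log2 Bre1a minus Bre1b, were Rnf20 (-1.94), Lce1i (-0.48), Postn (-2.83), Casp4 (-2.81), Ubd (-2.23), Ncf4 (-2.30), Trem2 (-0.88), Cxcl2 (-4.57), Fam180a (-1.42) and Serpinb2 (-1.68). Higher were Rnf40 (1.77), Kctd12b (5.22), Olfr1006 (2.78), Hdac11 (2.33), Gfpt2 (1.87), Tbx10 (1.85) and P2rx6 (2.70). Rnf20 and Rnf40 are the targets themselves. The other genes were named as extremes of a knockdown, a choice that favours a difference. Without the control term, or with the arrays scaled to the same spread, limma called none of these differences. Of the lists, 10 differed, by camera at the preset correlation. With an estimated correlation 0 did (adjusted p = 0.631 at the lowest). Medians of the difference were 0.32 for G2 and mitosis, 0.31 for homologous recombination, 0.21 for DNA replication, 0.20 for interferon, 0.10 for ribosomal proteins and 0.092 for oxidative phosphorylation. They were -0.66 for cytokines, -0.46 for histone genes, -0.38 for immediate early genes and -0.24 for p53 targets. The ribosomal median lies at the difference between the repeated values of the arrays, so it may hold no measured change.

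Cytokine and immediate early genes were lower with Bre1a than with Bre1b knockdown. Within each control the Bre1b array had the wider spread of ratios. The robust SD, from the median absolute deviation, was 0.451 against 0.378 for no knockdown and 0.666 against 0.492 for mock. Bre1b against no knockdown was thus narrower than Bre1a against mock. With all arrays set to the same spread the cytokine list stayed past the threshold (camera adjusted p = 4.87e-05), as did the immediate early list (adjusted p = 0.0067). For the immediate early list this argues against spread as the whole cause. The cytokine list had medians of -0.68 and -0.53 on the Bre1a arrays and 0.07 and -0.16 on the Bre1b arrays. Scaling could hardly end the cytokine call, so that test decides little. Within each control the cytokine shift lay on the narrower array, which itself argues against spread as the whole cause. With an estimated correlation neither list passed, with adjusted p = 0.631 and 0.631 as reported and 0.73 and 0.76 at the same spread. The image records of the knockdowns come from separate months, and with no month holding both, the list median of -0.66 cannot be told apart from a batch difference. An effect of the knockdowns themselves stays open as well.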

How the results depend on the processing

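The alternatives that used treat, left out spots by their value or scaled the arrays for the gene lists were added after the data were seen, and all others were set before. Of 207 gene values named above, 199 passed the threshold in the reported fit, and none changed direction under any alternative run. Ranked genes were chosen for the same sign on both values, so the absence of reversals was largely set by that choice. List members that the rule picked but the text leaves out were not recomputed. Among them Atf3 was at -1.42 and 0.44 on the Bre1a arrays, so leaving out 1 array can reverse it. Each target rests on 1 usable probe and 2 arrays, so leaving out an array or reading single probes could not test its level.

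Without the replicate block, which here is the control term, limma called 2 genes for Bre1a, 162 for Bre1b and 0 between the knockdowns (1286 at an unadjusted p under 0.05). The pairing comes from the labels, where the replicate number is the control. Leaving out the block changed no list call other than those given above. The contrast of the controls is taken within each knockdown, and the number cannot also be a block there because it is the factor tested. With an array left out no residual degree of freedom remains in the reported model, so those fits had no block, and the lone array is assumed to vary like the rest. They called 7 to 131 genes for Bre1a, 0 to 1142 for Bre1b (0 without either Bre1b array) and 0 to 70 between the knockdowns, and the controls had no such fit. Scaling to 1 spread gave 1521, 1628, 0 and 0 calls for Bre1a, Bre1b, their difference and the controls, with 530 higher and 991 lower for Bre1a. Quantile normalization gave 3037, 0 and 0 for the last 3 of these. The cause was not tested. In the reported fit the called genes named for the last 2 comparisons had adjusted p from 0.0372 to 0.0481.

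Single probes gave 6675, 10553, 0 and 0 calls over 18620 probes, which include unnamed ones. Genes with values on at least 3 arrays gave 0 for the controls, and the low-variation filter, with 4559 genes tested, gave 2271 for Bre1a and 0 for the controls. A threshold of 0.10 gave 4044 between the knockdowns and 3585 between the controls. Tested against 1.5-fold, 0, 373, 0 and 0 genes passed. Counts over 2-fold on both arrays (199 and 347) became 560 and 1087 at 1.5-fold, 60 and 109 at 3-fold, and 982 and 1507 over single probes. For gene lists, an estimated correlation left 0 calls in each of the 4 comparisons, fry gave 0 for all but Bre1a, scaling to 1 spread left 5 for the controls, and a single probe per gene ended 1 call in each comparison, given above. Over single probes the array correlations were 0.735 (Bre1a pair), 0.704 and 0.795 (same control), and 0.578 and 0.722 (neither shared), and without genes over 2-fold on any array the lower of the last became 0.105. Under the other alternatives the total counts stayed within 1.5 times the reported ones. In a single direction, quantile normalization gave 1094 higher for Bre1a, and the low-variation filter gave 1702 higher for Bre1b and 743 lower between the knockdowns. Signal over background is not known for these spots, so its limit on small ratios could not be given.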

Other observations

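The tests of dye bias on the shared genes and of the mock control were chosen after the results were seen. The tests on receptor genes and on spots at small whole-number ratios were chosen before. Leaving out spots at the repeated value, the comparison of receptor quartiles and the share over all genes were added after.

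Among genes at least 2-fold lower on all 4 arrays, several were not described above. Scara5 lay between -2.10 and -1.76, Bhlhe40 between -2.33 and -1.49 and Cebpa between -1.58 and -1.16. Bhlhe40 and Cebpa are transcription factors. Protocadherin genes Pcdhb19 (-2.95 to -1.17) and Pcdhb20 (-1.88 to -1.37) were low as well. Higher on all 4 arrays were Tcstv1 (1.12 to 6.64) and Tcstv3 (1.08 to 2.37), a gene pair known from early embryos, and the keratinocyte protein S100a7a (1.06 to 3.79). These genes were picked after their values were seen.

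Probes without a gene name behaved unlike named ones. Of 5662 with values on all 4 arrays, 421 were at least 2-fold lower and 225 at least 2-fold higher on all 4 (7.44% and 3.97%). Of 12958 named probes 68 and 23 were (0.525% and 0.177%). Arrays that share neither knockdown nor control correlated with r = 0.770 and 0.832 over unnamed probes, against 0.223 and 0.473 over named ones. What these spots hold is not known here.

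Arrays that share neither knockdown nor control correlated across named genes, which may reflect a common effect of losing either ligase or a technical trend. The 17 measured receptor genes of smell and taste, unlikely to be active in these cells, had medians below that of all genes on every array. The gap was -0.23 where it was smallest. This met the criterion set before for a bias of dim spots, a median off in the same direction on every array. By the quartile comparison added after, their upper quartile lay above the median of all genes on 3 arrays, so such a bias stays open. Leaving out those genes and spots at repeated or small whole-number ratios hardly moved the lower correlation (0.228 to 0.226). The criterion set before for a common effect, that the correlation keeps much of its size, was thus met. But leaving out spots that hardly move the correlation cannot tell the explanations apart, so this decides neither explanation. Among the genes at least 2-fold higher on all arrays 22.7% had a called difference between knockdowns or controls, and among those lower 34.5%, against 31.0% of all genes, which leaves open whether gene-specific dye bias is the whole cause. Without a dye swap, dye bias and a common effect of the knockdowns cannot be told apart for these genes.

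The mock control held lower levels of G2, mitosis and histone genes than cells without knockdown. Of the G2 and mitosis list 90.2% of genes were lower in both estimates, which share no array, and over all genes the estimates correlated with r = 0.602, which argues against independent noise of single spots as the whole cause. The list medians were -0.298 on the Bre1a arrays and -0.286 on the Bre1b arrays. For this list, that argues against noise of a single array that moves many genes together as the whole cause. Such noise on several arrays stays open, since the list was picked for its difference. The criterion against noise of a single array also asked for an adjusted p under 0.05 with an estimated correlation. The list had camera adjusted p = 0.683 there, so the criterion was not met. That test rests on 1 residual degree of freedom and cannot decide this. Fewer dividing cells in the mock culture may be a candidate explanation, but the DNA replication list was not called (camera adjusted p = 0.126), so this stays open, as does a direct effect of the mock treatment. The histone list was at -0.10 against no knockdown and 0.46 against mock on the Bre1a arrays, so its direction there depended on the control.

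After a fit of knockdown and control, the robust SD of what remained between arrays was 0.0793 in log2, against 0.332 for the difference between the controls and 0.361 for that between the knockdowns. Some values against a control changed sign with the control, such as Ifit1 on the Bre1a arrays at -1.22 and 1.04.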
